A study of Mus musculus with 10 samples.

How the data were processed

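The samples were livers of male mice of the same strain, 5 wild type and 5 double knockout for both macroH2A genes, on 10 arrays. Per the labels' protocols, the mice were 2 months old, were fasted overnight for about 16 h and were killed in the morning, total RNA was extracted with Trizol, and labelled cDNA (biotin) was made with the Ambion WT Expression Kit. The values used were the deposited table of log2 expression levels per probe set, made by the authors with Affymetrix Expression Console, per the submitters' processing notes. The summarisation algorithm, the normalization and the version of that program are not given in the sources used here. The quartiles of the 10 arrays lay within 0.05 of each other on the log2 scale, so the values had been normalized between arrays before deposit. Scanner files, detection calls and hybridisation dates were not analysed here, so background, saturation and batches could not be read from them. The number of arrays, not a sequencing depth, limits the precision.

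Probe sets were named through the platform annotation given with the series. Of 41345 rows, 23521 had exactly 1 gene symbol, 1814 had several and 16010 had none. The 25335 rows with at least 1 symbol were tested, with no filter on level and no further normalization, and genes were named only from rows with 1 symbol. Of 22180 genes with a probe set of their own, 21994 were matched by gene identifier to a RefSeq table of the assembly GRCm38.p6. That table gave chromosome membership and which genes neighbour each other. It also placed members of the gene lists that the annotation holds under another symbol. A gene with several probe sets was represented by the probe set with the highest mean over the 10 arrays.

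Double knockout livers were compared with wild-type livers in limma 3.58.1 under R 4.3.3 (lmFit and eBayes without trend or robust option, two-sided), with group as the only term and Benjamini-Hochberg adjustment over the 25335 probe sets. A probe set was called at an adjusted p under 0.05. The fit had 8 residual and 3.96 prior degrees of freedom. Gene lists were tested with limma's camera at the preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 39 lists that had at least 5 measured genes, out of 41 lists. These lists held 638 genes, of which 560 had a probe set of their own, 28 occurred only on probe sets with several symbols and 50 were on no named probe set. Per list, the members called over all probe sets and those called when adjusted over the list alone were counted. Camera with an estimated correlation and fry were run as alternatives, and an exact permutation test of the list means per array, chosen after the data were seen, was added. Its smallest possible p for 5 arrays against 5 is 0.00794, and its p-values were not adjusted over the lists. Genes within 5 Mb of either knocked-out gene were compared with all other genes by Fisher's exact test, two-sided. All X-linked genes formed a further camera list outside the adjustment.

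Comparisons, tests, lists and the rule for naming genes were fixed before the data were examined. Named were the knocked-out genes, then the 12 largest rises and 12 largest falls among called probe sets with 1 symbol whose groups did not overlap, and per list up to 4 called members by lowest p. For a list without a called member, up to 2 members of lowest p were named as values, and called genes near the knocked-out loci would also have been named. Predicted genes and olfactory or vomeronasal receptors were counted but not named; 19 called probe sets were of these kinds.

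The fits were tested on simulated data with the means and spreads of the 25335 real probe sets, for the comparison of double knockout with wild type. Of 68 probe sets changed by 0.3 on the log2 scale 55.9% were called, of 66 changed by 0.5 86.4% were, and of 66 changed by 1 100% were. Unchanged probe sets made up 5.1% of the calls, and a list shifted by 0.3 was the 1 list that passed. The simulated noise was drawn independently for each probe set, without the correlation between genes of real arrays. The simulation therefore does not show how often camera passes an unchanged list in these data.

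Alternatives were an intensity trend and the robust option in eBayes, array quality weights, quantile normalization applied again, median centring, a filter on low levels, testing every row or only rows with 1 symbol, the replicate number as a block, other thresholds, other list tests and leaving out each array in turn. After the data were seen, covariates for pancreas markers, macrophage markers and olfactory receptor probe sets were added, means of haemoglobin probe sets and of sex-biased genes served as covariates for list means, 15 macrophage markers outside the list were tested, as were fits without the 4 arrays with the highest pancreas marker means and without replicate 1 of both groups. The labels do not state in so many words that each sample came from a separate animal; if any did not, p-values measure in part a technical spread.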

Results

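Livers of adult mice lacking macroH2A1 and macroH2A2 were compared with wild-type livers after an overnight fast. MacroH2A proteins are variants of histone H2A that carry a large non-histone domain and are best known from the inactive X chromosome. The data were log2 expression levels of 41345 probe sets in 5 wild-type and 5 double knockout arrays, all from male mice aged 2 months and fasted for about 16 h. Median levels lay between 6.43 and 6.46 on the 10 arrays, and correlations between arrays ranged from 0.989 to 0.995, with 0 pairs of identical arrays. The median correlation was 0.993 within groups and 0.992 between groups. The 1108 probe sets of olfactory receptors, genes that liver is not known to use, had a median level of 4.63 and a 95th percentile of 6.54, and served as a guide to background.

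The knocked-out genes were examined in each array. The Macroh2a1 probe set fell by 0.49 on the log2 scale, from 9.60 ± 0.07 (SD, n = 5) in wild-type to 9.11 ± 0.07 (SD, n = 5) in double knockout livers (SE 0.05, limma adjusted p = 0.00128), and the 5 double knockout arrays, at 9.02 to 9.18, all lay below the 5 wild-type arrays, at 9.51 to 9.66. Macroh2a2 stood at 6.32 ± 0.28 (SD, n = 5) in wild-type and 6.12 ± 0.19 (SD, n = 5) in double knockout livers. Its log2 difference of -0.20 (SE 0.13) was not called (limma adjusted p = 0.514), and both means lay below the 95th percentile of the olfactory receptors. Each gene had 1 probe set. Where these probe sets lie relative to the deleted parts is not given in the sources used here, so a remaining signal does not measure remaining protein-coding transcript.

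**Figure D1:**
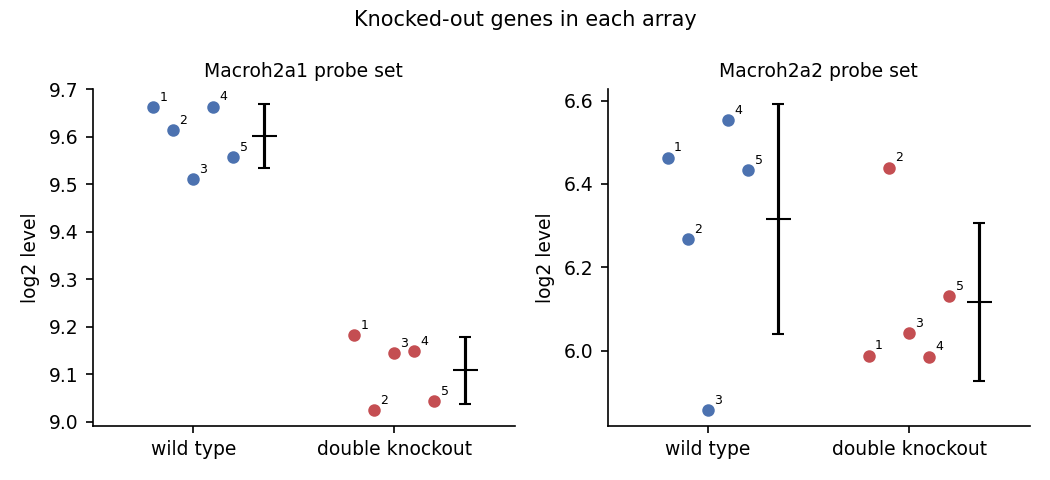
Log2 level of the Macroh2a1 and Macroh2a2 probe sets (vertical axes) in each of the 5 wild-type and 5 double knockout arrays, numbered by replicate; the bars give mean and SD. The groups are separate for Macroh2a1, at 9.51 to 9.66 against 9.02 to 9.18, and overlap for Macroh2a2.

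Of the 25335 probe sets tested, 224 were called, 84 higher and 140 lower in double knockout livers, and 214 of these had 1 gene symbol, naming 211 genes. Most changes were small: the median size was 1.29-fold, 45 reached 1.5-fold and 8 reached 2-fold, 4 in each direction. At an unadjusted p under 0.05 there were 3829 probe sets, where 1267 are expected by chance. The groups did not overlap for 3.90% of tested probe sets, against 0.794% expected by chance, and for 216 of the 224 called. Of the calls, 21 (9.38%) lay below the 95th percentile of the olfactory receptors, while 55.6% of tested probe sets lay above it. The mean level of the olfactory receptor probe sets was 4.80 ± 0.03 (SD, n = 5) in wild-type and 4.87 ± 0.06 (SD, n = 5) in double knockout arrays (exact permutation p = 0.0556), and with this mean as a covariate 53 probe sets were called. More calls were lower than higher, but this turned to 126 higher and 96 lower without wild-type replicate 1, 133 and 120 without double knockout replicate 1, and 460 and 153 without both. Leaving out 1 array gave 64 calls without wild-type replicate 2, 144 without wild-type replicate 3 and 131 without wild-type replicate 4, and 135, 124, 68 and 87 without double knockout replicates 2, 3, 4 and 5.

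The largest rise was that of Fabp5, a fatty acid-binding protein, from 6.68 ± 0.42 to 8.51 ± 0.70 (SD, n = 5 each), a log2 change of 1.84 (SE 0.30, limma adjusted p = 0.0209). Its 4 probe sets were all higher, by 0.19 to 1.85, and 3 of them were called. Sdf2l1, a component of a chaperone complex of the endoplasmic reticulum, rose by 1.41 (SE 0.14, limma adjusted p = 0.00128). Lpl, lipoprotein lipase, rose by 1.13 (SE 0.15, limma adjusted p = 0.00687), while its second probe set, at a mean level of 4.50, had a log2 difference of 0.07. Next came Cyp39a1, an oxysterol hydroxylase, with 0.93 (SE 0.13), Slc22a26, an organic anion transporter, with 0.89 (SE 0.11), Meig1, known from spermatogenesis, with 0.85 (SE 0.07), Krt23, a keratin, with 0.84 (SE 0.13), and the microRNA gene Mir680-1, with 0.82 (SE 0.11). Creld2 (0.76, SE 0.10), Ero1b (0.75, SE 0.09) and Hyou1 (0.68, SE 0.08), all of the endoplasmic reticulum, and the tetraspanin Tspan33 (0.65, SE 0.08) completed the 12 largest rises. The limma adjusted p of these 9 genes lay between 0.000884 for Meig1 and 0.0161 for Krt23.

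The largest fall was that of Obp2a, an odorant-binding protein of the lipocalin family, from 11.73 ± 0.70 to 9.05 ± 0.72 (SD, n = 5 each), a log2 change of -2.68 (SE 0.37, limma adjusted p = 0.00733). Mup21, a major urinary protein of the same family, fell by 1.59 (SE 0.23, limma adjusted p = 0.00915). Sucnr1, the succinate receptor, fell by 0.89 (SE 0.07) and had the lowest adjusted p of all probe sets, 0.000655 in limma. Ddah1, which breaks down asymmetric dimethylarginine, fell by 0.88 (SE 0.15), the kinase Mapk15 by 0.79 (SE 0.10) and Dop1b by 0.76 (SE 0.10). Car3, a carbonic anhydrase, had a change of -0.75 (SE 0.11), with -0.61 on its other probe set, and Car1, of the same family, -0.69 (SE 0.12). Aqp8, a water channel, had a change of -0.75 (SE 0.15), the carboxylesterase Ces1g -0.72 (SE 0.14) and the complement component C6 -0.71 (SE 0.10). For these 9 genes limma adjusted p ran from 0.000655 to 0.0475, the highest being that of Aqp8. Arfip1 was among the 12 by 1 of its 3 probe sets, with -1.08 (SE 0.15, limma adjusted p = 0.00786). Its probe set with the highest mean had -0.003 (limma adjusted p = 0.989), and the third had 0.13. Members of the urinary protein, carboxylesterase and carbonic anhydrase families are similar in sequence, and how far their probe sets tell them apart was not tested.

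Of these genes other than Arfip1, Fabp5 and Krt23 among the rises and Ddah1, Car1, Ces1g and Aqp8 among the falls lost their call in at least 1 of the 10 fits without an array. Fabp5 had adjusted p up to 0.063, Krt23 up to 0.0556, Ddah1 up to 0.0636, Car1 up to 0.0619, Ces1g up to 0.0941 and Aqp8 up to 0.123 in limma, and 0 of them changed sign. With the macrophage marker mean as a covariate, chosen after the data were seen, 30 of the 35 called named genes lost their call, and Sdf2l1, Meig1, Ero1b, Hyou1 and Sucnr1 stayed called. This mean was itself higher in double knockout arrays, so as a covariate it stands in part for the genotype. Among those lost, Obp2a had -3.28 (SE 0.51) and Mup21 -1.997 (SE 0.31), no smaller than without the covariate but with a larger SE, while Fabp5 had 1.31 (SE 0.41), Lpl 0.78 (SE 0.19) and Cyp39a1 0.79 (SE 0.20), smaller than without it. Hyou1 lost its call without the 4 arrays of highest pancreas marker mean, with 0.65 (SE 0.10).

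Chaperone genes had higher means as a group. All 18 measured members of the unfolded protein response and heat shock list had higher means in double knockout livers, with a mean log2 difference of 0.48, and 8 were called, or 16 adjusted over the list alone. The list mean per array was 9.82 ± 0.09 in wild-type and 10.29 ± 0.13 in double knockout livers (SD, n = 5 each), with every double knockout array above every wild-type array (exact permutation p = 0.00794, the smallest possible). The called members all act in the endoplasmic reticulum. Sdf2l1, Hyou1, Creld2 and the co-chaperone Dnajb9 (0.53, SE 0.07, limma adjusted p = 0.00444) had the lowest p, and Hspa5, Manf, Hsp90b1 and Calr were called with 0.58, 0.63, 0.33 and 0.28. Heat shock genes of the cytosol had values such as 0.78 for Hspa1b, 0.64 for Hsph1 and 0.45 for Hspb1 and were not called. The last 7 genes were chosen for the text after their values were seen. In camera the list had an adjusted p = 7.85e-24, and an adjusted p = 0.129 with an estimated correlation.

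**Figure D2:**
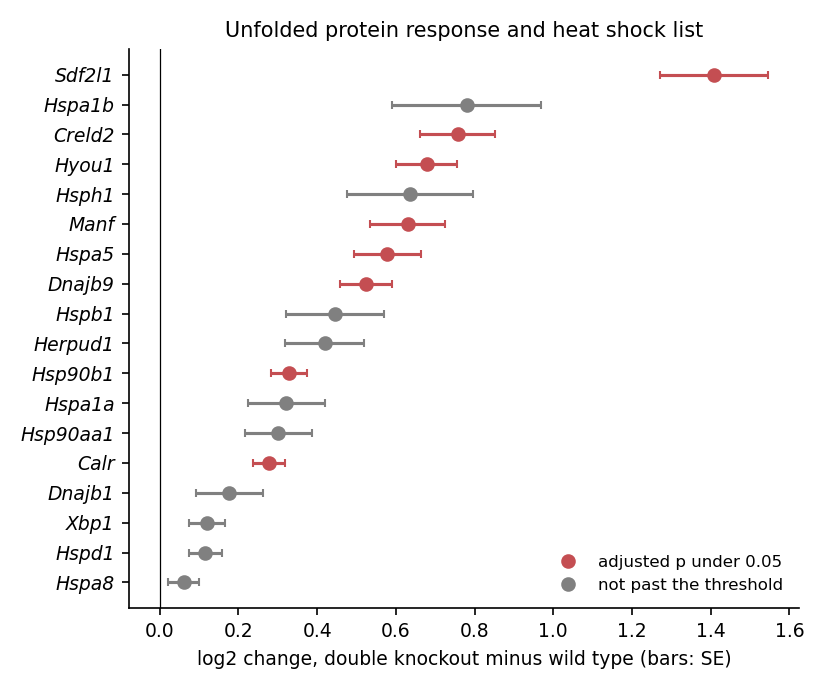
Log2 change from wild type to double knockout (horizontal axis) with its SE for the 18 measured genes of the unfolded protein response and heat shock list, 5 arrays per group; colour marks the 8 called genes. All 18 points lie above 0, up to 1.41 for Sdf2l1.

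Macrophage markers were also higher. All 15 members of the Kupffer cell and macrophage list had higher means in double knockout livers, with a mean log2 change of 0.23, and 2 were called, the scavenger receptors Cd163 (0.45, SE 0.08, limma adjusted p = 0.0284) and Marco (0.61, SE 0.13, limma adjusted p = 0.0475), or 6 adjusted over the list alone. The camera adjusted p was 1.98e-08, and an adjusted p = 0.622 with an estimated correlation. The list mean per array was 8.56 ± 0.11 in wild-type and 8.79 ± 0.13 in double knockout livers (SD, n = 5 each, exact permutation p = 0.0238). Without single arrays, Cd163 lost its call in 4 of 10 fits (adjusted p up to 0.087) and Marco in 8 (up to 0.118).

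Markers of other cell types did not pass. Of 12 endothelial markers 8 had higher means (camera adjusted p = 0.445), with values of 0.13 for Cdh5 and 0.12 for Pecam1. Among 14 stellate cell and fibroblast markers 6 had higher means (adjusted p = 0.454), with -0.17 for Reln and -0.17 for Colec11, and 1 was lower adjusted over the list alone. Cholangiocyte markers were higher for 7 of 9 members (adjusted p = 0.347), with 1 called, Krt23, also adjusted over the list alone. T and NK cell markers had higher means for 8 of 13 (adjusted p = 0.445; Ccl5 0.28, Cd3g 0.14), B and plasma cell markers for 3 of 9 (adjusted p = 0.401; Cd79b -0.28, Sdc1 -0.21, with 0.01 on a second probe set of Sdc1) and neutrophil markers for 5 of 11 (adjusted p = 0.70; S100a9 0.13, Ly6g -0.11). Adipocyte markers had higher means for 2 of 7 (adjusted p = 0.384), with Car3 called and 2 lower adjusted over the list alone. Muscle markers had higher means for 6 of 10 (adjusted p = 0.862; Myl1 -0.09, Mylpf 0.06). Only 4 erythroid markers had a probe set of their own, too few to test, with values of -0.26 for Tfrc and 0.10 for Epb42. The 5 probe sets shared between haemoglobin genes, examined after the values were seen, all had higher means in double knockout livers, by 0.37 to 1.66. Of these, 1 was called (0.66, SE 0.11, limma adjusted p = 0.0241), and the other 4 had limma adjusted p from 0.0526 to 0.0738. Hepatocyte markers had higher means for 3 of 12 (adjusted p = 0.73; Serpina1a -0.11, Hnf4a 0.05).

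Pancreas markers differed between arrays within each group. Their mean was 9.43 and 10.36 in wild-type replicates 4 and 5, 8.32 and 8.49 in double knockout replicates 1 and 2 and 6.68 in double knockout replicate 4, against 6.07 to 6.21 in the other 5 arrays. Between the groups, 9 of 11 members had lower means in double knockout livers, with a mean log2 difference of -0.49 (camera adjusted p = 0.457). The 2 members of lowest p were Try5, with 0.12, and Prss2, with -1.05 (SE 0.69, limma adjusted p = 0.523). With the pancreas marker mean as a covariate 217 probe sets were called, and without the 4 arrays of highest mean 68 were.

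**Figure D3:**
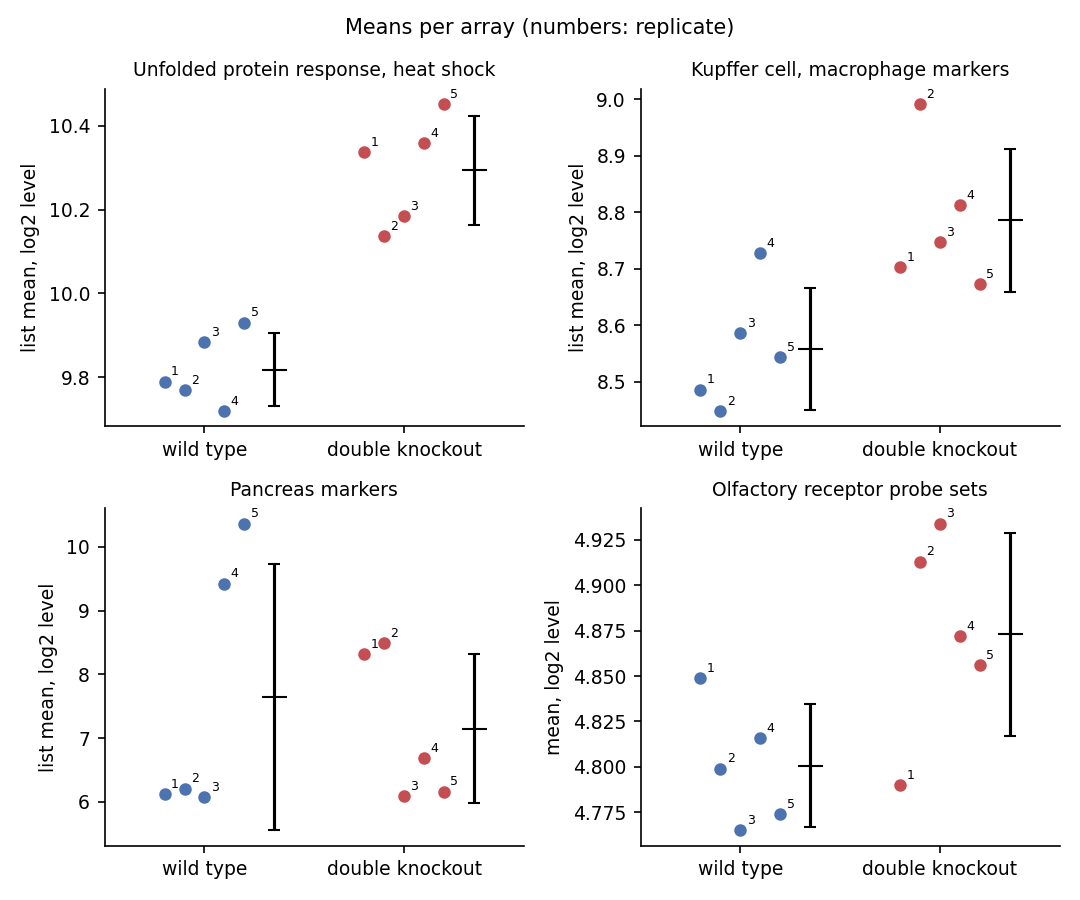
Mean log2 level (vertical axes) of the unfolded protein response and heat shock list, the macrophage markers, the pancreas markers and the olfactory receptor probe sets in each array, numbered by replicate; the bars give mean and SD of 5 arrays. The chaperone list is separate between the groups, and pancreas markers are high in wild-type replicates 4 and 5 and double knockout replicates 1 and 2.

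In addition, 2 lists passed with lower means in double knockout livers. In the PARP and NAD metabolism list, 15 of 17 measured members had lower means, with a mean log2 change of -0.11 (camera adjusted p = 0.00963, adjusted p = 0.622 with an estimated correlation). The exact permutation p of its list means per array was 0.0238, not adjusted over the lists. Some lists that did not pass in camera had exact permutation p of like size: 0.03175 for female-biased liver genes and 0.03968 each for the circadian clock and the integrated stress response. Haao, an enzyme of the kynurenine route to NAD, was called with -0.22 (SE 0.04, limma adjusted p = 0.0402), and 2 members passed adjusted over the list alone. The Haao call was lost in all 10 fits that left out 1 array (adjusted p up to 0.10). In the cholesterol synthesis and uptake list, 15 of 17 had lower means, with a mean of -0.13 (camera adjusted p = 0.0387, adjusted p = 0.747 with an estimated correlation). The list mean per array was 9.50 ± 0.26 in wild-type and 9.37 ± 0.17 in double knockout livers (SD, n = 5 each, exact permutation p = 0.373). This list had 0 called members, also adjusted over the list alone. In limma Sc5d had -0.18 (adjusted p = 0.185) and Insig1 -0.36 (adjusted p = 0.307). The cholesterol list did not pass without wild-type replicate 1 or 3 or double knockout replicate 3, 4 or 5, with list means from -0.21 to -0.04 and adjusted p up to 0.542 over the 10 fits.

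The other 35 lists did not pass, with adjusted p from 0.0899 to 0.862, and single genes in them were called. Of 27 fatty acid oxidation and PPARalpha genes, 16 had higher means (camera adjusted p = 0.375), and Cyp4a31, a fatty acid hydroxylase, was called with 0.27 (SE 0.06); 3 were higher adjusted over the list alone. Among 19 genes of lipid droplets, lipases and lipoproteins (adjusted p = 0.445), Lpl was called higher and Apoa5, an apolipoprotein of triglyceride metabolism, lower with -0.26 (SE 0.05); 1 was higher and 2 were lower adjusted over the list alone. Gluconeogenesis and glycogen breakdown had lower means for 11 of 14 (adjusted p = 0.158; Gpt -0.33, Fbp1 -0.12), glycolysis and glycogen synthesis for 8 of 10 (adjusted p = 0.445; Pfkfb3 0.28, Slc2a2 -0.14; 1 higher adjusted over the list alone) and fatty acid and triglyceride synthesis for 14 of 19 (adjusted p = 0.176; Acly -0.24, Acacb 0.38; 1 higher and 1 lower adjusted over the list alone). Ketogenesis and ketone use had higher means for 2 of 5 (adjusted p = 0.862; Slc16a1 0.26, Slc16a6 -0.14), with 1 higher adjusted over the list alone. Bile acid synthesis and transport had lower means for 11 of 17 (adjusted p = 0.445; Abcc3 -0.24, Cyp7b1 0.27), with 1 higher and 1 lower adjusted over the list alone. Xenobiotic metabolism had higher means for 10 of 22 (adjusted p = 0.862; Cyp2a5 -0.76, Cyp3a11 0.34), with 2 higher and 3 lower adjusted over the list alone. NRF2 targets had higher means for 6 of 13 (camera adjusted p = 0.445, with Abcc4 0.33 and Osgin1 0.84), with 3 higher and 1 lower adjusted over the list alone. For NRF2 targets every double knockout array had a higher list mean than every wild-type array (exact permutation p = 0.00794, not adjusted over the lists). The mitochondrial respiratory chain had higher means for 8 of 18 (adjusted p = 0.73; Ndufv1 -0.10, Sdha -0.10).

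Among hormone and rhythm lists, female-biased liver genes had higher means for 12 of 19 (camera adjusted p = 0.0899), with Cyp39a1 called and 3 higher adjusted over the list alone. Male-biased liver genes had lower means for 11 of 18 (adjusted p = 0.439), with Mup21 and C6 called and 4 higher and 4 lower adjusted over the list alone. In the growth hormone and IGF list (7 of 14 higher, adjusted p = 0.73) the growth hormone receptor Ghr fell by 0.30 (SE 0.05, limma adjusted p = 0.0212) and Igfbp2 rose by 0.31 (SE 0.06, limma adjusted p = 0.0361), with 2 higher and 2 lower adjusted over the list alone. Circadian clock genes had lower means for 13 of 20 (adjusted p = 0.185). The clock repressor Nr1d2 was called with -0.38 (SE 0.08, limma adjusted p = 0.0461), and 3 were higher and 7 lower adjusted over the list alone. Thyroid hormone genes had higher means for 5 of 14 (adjusted p = 0.763). Serpina7, the thyroxine-binding globulin, stood at 7.21 ± 0.64 and 8.38 ± 0.52 (SD, n = 5 each), a difference of 1.16 that was not called (limma adjusted p = 0.0999), and Thra had -0.16; 1 member was higher adjusted over the list alone. Glucocorticoid response genes had higher means for 5 of 15 (adjusted p = 0.445; Irs2 0.52, Mt1 -0.58), with 2 higher and 3 lower adjusted over the list alone.

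In the remaining lists, the integrated stress response had higher means for 11 of 18 members (camera adjusted p = 0.298; Atf5 0.26, Asns 0.60; 1 higher adjusted over the list alone), the interferon response for 8 of 20 (adjusted p = 0.862; Oasl1 -0.20, Ifit1 -0.34) and acute phase and inflammation for 7 of 21 (adjusted p = 0.862; Steap4 -0.28, Apcs 0.29). Cell cycle genes had higher means for 11 of 23 (adjusted p = 0.862; Top2a 0.20, Mcm4 -0.17) and p53 targets and senescence for 6 of 13 (adjusted p = 0.584; Fas -0.11, Cdkn2b -0.11). Other histone variants and linker histones had higher means for 3 of 8 (adjusted p = 0.667; H2ax 0.20, H1f10 -0.13). Fetal liver and imprinted growth genes had higher means for 8 of 17 (adjusted p = 0.699), and Alpl, alkaline phosphatase, was called with 0.26 (SE 0.05), also adjusted over the list alone. Pericentral hepatocyte markers had higher means for 5 of 12 (adjusted p = 0.445), with the ammonium transporter Rhbg called at 0.58 (SE 0.10) and 2 higher and 3 lower adjusted over the list alone. Periportal hepatocyte markers had higher means for 2 of 9 (adjusted p = 0.445), with the immunoglobulin receptor Pigr called at -0.22 (SE 0.04) and 1 higher and 1 lower adjusted over the list alone. The mean, median and test direction differed in sign for ketogenesis, xenobiotic metabolism, NRF2 targets, thyroid hormone, acute phase, cell cycle, fetal liver, neutrophil and X-linked lists. Without single arrays, the calls of Cyp4a31, Alpl, Nr1d2 and Pigr held in 1 of 10 fits each, those of Apoa5 in 2, Igfbp2 in 3, Rhbg in 4 and Ghr in 7.

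**Figure D4:**
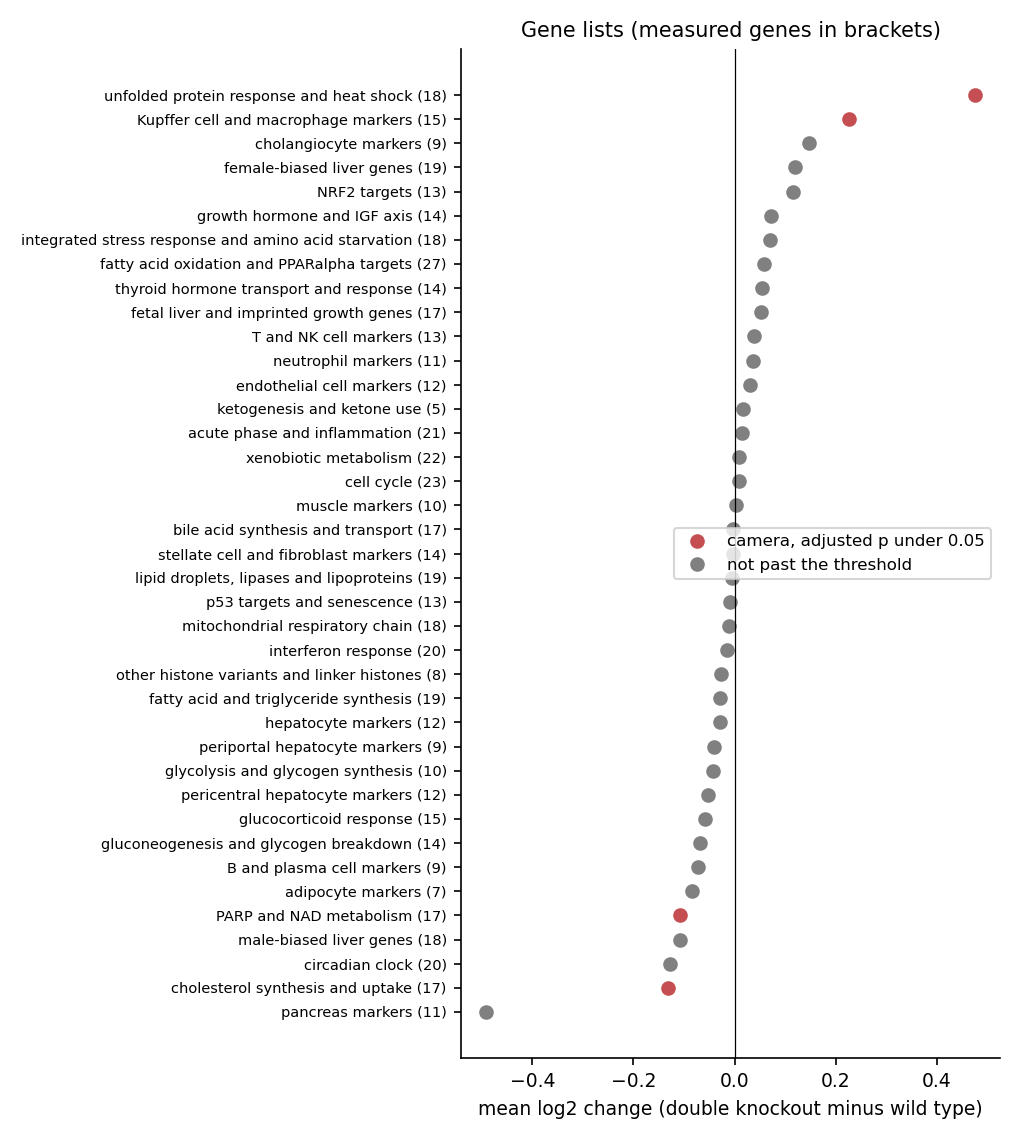
Mean log2 change from wild type to double knockout (horizontal axis) of the measured genes in each of the 39 tested lists, 5 arrays per group; colour marks the 4 lists past the camera threshold. The unfolded protein response and heat shock list lies highest at 0.48.

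Genes near the knocked-out loci were compared with all others, because a knockout can carry flanking sequence or affect neighbours. Of 206 genes within 5 Mb of either locus 0 were called, against 206 of 21786 other genes (Fisher's exact p = 0.271). X-linked genes were tested because of the known place of macroH2A on the inactive X chromosome, which males lack. The 899 measured X-linked genes had a mean log2 difference of 0.005 and a median of -0.002 (camera p = 0.486; exact permutation p of the array means = 0.167), with 440 higher, 459 lower and 2 called, both lower.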

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

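Chosen only after the result was seen were the splits for the number of called probe sets, the tests of hepatocyte share and macrophage number, those with macrophage, haemoglobin or sex-biased means as covariates, and both tests of the exchanged arrays. Of 262 groups of 5 arrays, for named genes and list means, 20 held an array far from the other 4, where about 13.1 (1 in 20) are expected by chance. Among called genes these were Cyp39a1 in double knockout replicate 2 (11.793, others 12 to 12.05), Creld2 (10.304, others 10.062 to 10.121) and Hyou1 (9.317, others 9.055 to 9.103) in wild-type replicate 3, Ces1g in double knockout replicate 3 (8.65, others 9.153 to 9.336), Haao in wild-type replicate 4 (12.602, others 12.45 to 12.48) and Pigr in double knockout replicate 4 (12.192, others 12.29 to 12.325). Among genes not called, wild-type arrays stood apart for Slc2a2 (replicate 1, 11.822, others 11.527 to 11.612), Serpina7 (replicate 1, 8.339, others 6.765 to 7.007), Ndufv1 (replicate 5, 11.866, others 11.981 to 12.016), Pecam1 (replicate 4, 8.739, others 8.908 to 8.961) and Try5 (replicate 4, 4.567, others 4.288 to 4.347). Double knockout arrays stood apart for H2ax (replicate 4, 8.501, others 8.181 to 8.262), Sc5d (replicate 2, 12.237, others 12.046 to 12.085), Apcs (replicate 2, 10.858, others 9.81 to 10.056) and Ly6g (replicate 2, 4.818, others 5.065 to 5.142).

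List means far from the other 4 arrays were those of glycolysis and glycogen synthesis (double knockout replicate 5, 10.513, others 10.587 to 10.612), NRF2 targets (wild-type replicate 3, 9.176, others 9.275 to 9.299), circadian clock (wild-type replicate 1, 8.54, others 8.684 to 8.728), cholangiocyte markers (double knockout replicate 3, 6.958, others 7.283 to 7.379) and T and NK cell markers (double knockout replicate 2, 6.163, others 5.974 to 6.011). Among the 16010 probe sets without a gene symbol, which the comparisons leave out, 11 were called when every probe set was tested, 4 higher and 7 lower in double knockout livers.

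The 10 arrays were also split 5 against 5 in other ways, with 100 of the 126 distinct splits drawn, the real split among them. In 2 of the 100 splits, the real one included, at least 224 probe sets were called; the highest count in another split was 352, and 97 of the other splits had 0 calls. At least 4 lists passed in 64 of 100, up to 14, so the number of passing lists was no larger than regrouped arrays gave. The X-linked shift was at least as large in 19 of 100, and 0 calls near the knocked-out loci was met or exceeded in 100 of 100, which says nothing.

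The difference of the chaperone list, 0.476 (SE 0.07), was set against 6 other differences between the samples, each as a covariate. It was 0.474 with the pancreas marker mean, 0.509 with the fatty acid oxidation list as a measure of feeding state, 0.417 with the main axis of the clock genes as a measure of the time of killing and 0.591 with the macrophage marker mean. The bounds 2 SE below these values, 0.323, 0.316, 0.308 and 0.407, lay above 0.238, so these 4, as far as the markers measure them, do not account for most of the difference. With the mean of the haemoglobin probe sets it was 0.358 (SE 0.12, lower bound 0.119) and with the female-biased minus male-biased mean 0.357 (SE 0.08, lower bound 0.197), and both bounds lay below 0.238. More blood in the double knockout samples therefore stays open as a part of the difference, beside the genotype and what was not measured. The 4 erythroid markers with a probe set of their own had a mean of 6.77 in wild-type and 6.75 in double knockout livers. Of these, 2 had higher and 2 had lower means. The sex-biased mean holds Cyp39a1, Mup21 and C6, which were called between these same groups. As a covariate it stands in part for the genotype, so this test cannot decide on a shift in sex-biased expression.

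For the higher macrophage markers, a lower share of hepatocytes would raise all non-hepatocyte markers, yet endothelial and stellate markers shifted by 0.012 (SE 0.034), against the 0.114 that this explanation required. Of 15 macrophage markers outside the list 13 had higher means and 0 were called in limma. Together they shifted by 0.151 (SE 0.069, exact permutation p = 0.0556), above 0.114 by less than the SE. More macrophages would give a shift in this direction, though higher expression per cell would give it too. At this precision the test does not settle whether there were more macrophages. The shift was uneven over the markers, from -0.026 for Aif1, -0.019 for Clec1b and 0.051 for Folr2 to 0.352 for Tyrobp and 0.391 for Ctss. The difference of the macrophage list was 0.227 (SE 0.074) without a covariate and 0.245 (SE 0.07, lower bound 0.106) with the pancreas marker mean. Pancreas markers, at 7.64 in wild-type and 7.15 in double knockout arrays, thus did not lower it, though the bound lay below 0.114. With the haemoglobin mean the difference was 0.222 (SE 0.14, lower bound -0.059). At this precision the tests did not settle a part played by pancreas RNA or blood.

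The split with 352 calls exchanged replicate 1 of the groups, placing wild-type replicate 1 with double knockout replicates 2 to 5. Mislabelled arrays do not explain it, since Macroh2a1 stood at 9.662 in wild-type replicate 1, inside the wild-type range. Its calls were mostly of low or shared signal. Of them, 340 were higher on the side of double knockout replicates 2 to 5 and 233 had several symbols. Olfactory or vomeronasal receptors made up 50, 23 lay on the Y chromosome, and 5 were also called in the real comparison. The mean of the 1071 olfactory receptor probe sets not called in it differed by 0.0835 between its sides. A background signal that differs between arrays would give such a difference. The split was chosen for its calls, which already held such receptors, so this test is not independent of them and does not decide on the cause. Over the same 1071 probe sets the real groups differed by 0.0635 (exact permutation p = 0.0556), with the higher mean in double knockout arrays. The real calls were of another kind: 10 had several symbols and 7 were olfactory or vomeronasal receptors. Of the 224 real calls, 140 were lower in double knockout livers, against the direction of this mean. A part of the small real differences could still come from such a background, and no biological explanation was tested.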

How the results depend on the processing

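Alternatives chosen only after the data were seen were the 3 covariates (pancreas, macrophage and olfactory receptor means) and the fits without 4 pancreas-rich arrays or without replicate 1 of both groups. Against 224 calls in the comparison as reported, 439 probe sets were called among those at or above the median level, 75 when every probe set was tested, 585 at an adjusted p under 0.1, 45 under 0.01 and 45 with at least 1.5-fold change. The count was 17 with the macrophage covariate, 53 with the olfactory receptor covariate, 68 without the 4 arrays of highest pancreas marker mean and 613 (460 higher, 153 lower) without replicate 1 of both groups. The cause was not tested. The macrophage mean itself differed between wild-type and double knockout arrays (8.56 and 8.79, exact permutation p = 0.0238) and holds the called genes Cd163 and Marco. As a covariate it stands in part for the genotype, so the smaller count does not separate the 2. Other tests, weights and normalizations gave 212 to 291. Leaving out 1 array gave 64 to 253, with 56.8% of calls higher without wild-type replicate 1 and 52.6% without double knockout replicate 1, against 37.5%.

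Macroh2a1 lay between -0.516 and -0.465 in 24 alternatives and lost its call in 1, the macrophage covariate (-0.465, adjusted p = 0.0539); without single arrays it was -0.516 to -0.472. Macroh2a2 lay between -0.393 (macrophage covariate) and -0.128 in 23 alternatives, with -0.381 with the olfactory receptor covariate and -0.312 to -0.138 without single arrays, and was called in 0 of them in limma; the level filter removed it. Calls near the loci were 0 in the 10 fits without single arrays and within 2 Mb and 10 Mb, and the X-linked mean was 0.003 to 0.007 without single arrays; the other alternatives were not run for these results, except an estimated correlation for the X-linked genes (limma camera p = 0.253).

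Of 4 lists as reported, 2 passed after quantile normalization was applied again, 1 (chaperones) with fry and 0 with an estimated correlation; without single arrays 3 to 8 passed. Over 25 alternatives the chaperone mean was 0.436 to 0.592 (adjusted p 1.23e-29 to 0.129) and the list passed in 24. The macrophage list passed in 23 (0.171 to 0.269, adjusted p 1.34e-11 to 0.622), PARP and NAD in 22 (-0.142 to -0.077, 0.0027 to 0.622) and cholesterol in 15 (-0.393 to -0.035, 8.6e-12 to 0.747). The robust option gives no separate list test, and camera was not run on the lists with the macrophage covariate.

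With the replicate number as a block 76 probe sets were called and 5 lists passed; correlations of same-numbered arrays, -0.477 to 0.131, with 0 of 5 best matched to their own number, give no sign of pairing.

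Of 35 called named genes, 4 (Ero1b, Meig1, Sdf2l1 and Sucnr1) stayed called in every alternative that measured them, and 0 changed sign. With the macrophage covariate 30 lost their call, with the olfactory receptor covariate 23, and without the 4 pancreas-rich arrays 23. The lost genes kept a median of 1.004, 0.991 and 0.981 times their log2 change, while their SE was 1.45, 1.33 and 1.23 times as large in the median, so in the median the losses came with a wider error rather than a smaller change. With the macrophage covariate, 15 of the 30 lost genes kept at least their full log2 change and the others shrank. Among these, Aqp8 kept 0.627 times its change, Lpl 0.69 and Fabp5 0.716. The lowest was 0.368 times for Marco, itself part of the covariate. Without single arrays 18 kept their call in all 10 fits, 6 in 5 to 9 and 11 in fewer. Of the 53 named genes not called, 25 combinations of gene and alternative passed, and 11 combinations of another list and an alternative did. No result past the threshold reversed. Of the 224 calls, 21 (9.38%) lay below the 95th percentile of the olfactory receptors, while only 55.6% of tested probe sets lay above it. Calls were thus rarer among probe sets of low signal.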

Other observations

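The neighbour and sex-pattern ideas arose from the lists of called genes; the sex score was chosen only after the result was seen, and the genes named in this paragraph were picked from the calls after their values were seen, without a group test. Beyond the list, further genes of protein folding and transport in the endoplasmic reticulum rose: Dnajb11 by 0.42, Slc35b1 by 0.43, Pdia6 by 0.45, Pdia3 by 0.28, Syvn1 by 0.37, Ostc by 0.32 and the calcium pump Atp2a2 by 0.30 (limma adjusted p from 0.00444 to 0.0365). Among carboxylesterase genes, Ces1e (-0.62), Ces2e (-0.45) and Ces1f (-0.35) fell and Ces4a rose by 0.62 (limma adjusted p up to 0.041). The receptors Smo (-0.59) and S1pr1 (-0.56) and 2 genes of fructose and glucose handling, Khk (-0.36) and Gckr (-0.33), fell, and the nuclear pore gene Nup210 rose by 0.58 (limma adjusted p from 0.000973 to 0.0364).

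Called genes that neighbour each other could mark chromosome segments that differ between the groups. Of 206 called genes 58 had a called neighbour, against a median of 57 and a 95th percentile of 70 when the called genes were permuted 10000 times among genes of like level (permutation p = 0.458), and 17 of 34 pairs moved the same way. This test gave no sign of such segments and, at this number of genes, does not exclude a few.

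Cyp39a1 rose and Mup21 and C6 fell, as in a shift toward female-pattern expression. The mean of female-biased minus male-biased genes was -3.51 ± 0.06 (SD, n = 5) in wild-type and -3.28 ± 0.18 (SD, n = 5) in double knockout livers (exact permutation p = 0.0159). The score holds the 3 genes that prompted it, and without them the difference fell from 0.228 to 0.053 (exact permutation p = 0.579). The score thus restated these 3 changes and left a wider shift undecided. In camera neither list passed on its own in the comparison as reported. The female-biased list did pass in some alternatives, such as the level filter (camera adjusted p = 0.0439) and the replicate block (camera adjusted p = 0.0462).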
